A study of Mus musculus with 6 samples.

How the data were processed

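RNA sequencing was available for 6 libraries of mouse liver, 3 from knockout and 3 from wild-type mice, each taken 6 h after LPS at 15 mg/kg. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries by a standard Illumina procedure; the descriptions also carry the words 10x Genomics, but the table holds tissue libraries and no cells. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5, and the builds mm39 and hg38 are named without a role. The counting tool, its strand setting, its treatment of reads with several matches, the annotation and any filter are not given in the sources used here.

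The deposited FPKM values (fragments scaled by gene length and by the mapped fragments of the library, by the authors) form a single table of 19613 rows with 19591 distinct gene symbols and 6 columns, matched to the samples by the library names in the labels. The table has 412 rows at 0 in every library and no unused columns of values. Rows that share a symbol (42) were kept apart. FPKM sums ranged from 327641 in WT replicate 1 to 576649 in KO replicate 3, and the deposited values carry no record of a scaling between libraries.

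Within a library, the FPKM of a gene is a whole number of reads times a step set by the gene's length and the library's denominator. The relative denominators were taken from the most frequent ratio of low values between libraries. Each gene's reads were taken as the smallest whole numbers that give its values in all 6 libraries, to within 0.0001 reads of a whole number. This worked for 19612 of the 19613 rows (99.99%), all but COX1, and the counts stand up to a factor common to all libraries of a gene. On 18745 simulated genes, 97.5% of the counts came back exactly. Gene lengths were compared with the exonic lengths of GENCODE M21 (GRCm38, a different build from mm39, so no coordinates are given); between 94.2% and 94.4% of the genes agreed within 0.5 bp, which sets the absolute size of each denominator. The reads recovered made up 92.2%, 109.6% and 121.4% of the implied denominator in KO replicates 1 to 3 and 71.3%, 69.0% and 89.7% in WT replicates 1 to 3. The reads recovered in genes came to 24087946 to 41638311 per library, and counting error weighs most on the lowest genes. These totals and the shares of the denominator leave out COX1.

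Because the unit is FPKM, no count model was the main test. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries (9218) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided) on log2(FPKM + 1), genotype as the only term and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg and genes called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The fit on the deposited values, its alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The fit on values divided by median-of-ratios factors was 1 of the alternatives fixed then; it was given the weight of a second result, with its own alternatives, only after the data had been seen, because the deposited values shifted the median of all genes by 0.45. On 9218 genes simulated with the data's library scale differences, limma called 1055 unchanged genes on the deposited values and 8 on the scaled values. It recovered 60% and 79% of genes changed by 1 on the log2 scale and 100% and 97% of those changed by 2. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery among lower genes was not simulated.

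Of 53 fixed gene lists, 45 had at least 5 tested members and were tested with limma's camera (preset correlation 0.01), adjusted over the 45. Named genes were the 10 largest rises and the 10 largest falls among called genes without overlap between the groups and with a mean of at least 1 FPKM (predicted genes and pseudogenes left out; without that, 2 of the 10 largest rises and 3 of the 10 largest falls would be such), 12 fixed genes, and the 3 members of lowest p of each list called by camera in the deposited values, with the 3 most abundant members of marker lists. The rule also covered lists with any called member; under the shift that meant nearly every list, and this part was narrowed, after the values were seen, to the 10 lists called by camera. The targeted gene, and results that need it, are not reported here. Other named genes are said to have been chosen after their values were seen. For single fixed genes an exact permutation test over the 20 assignments of the libraries has a smallest two-sided p of 0.1.

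Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 FPKM, scaling by median of ratios, upper quartile, quantiles or to TPM, eBayes without trend or robust, arrayWeights, the replicate number as a block, each library left out, an adjusted p under 0.1, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Added after the data were seen were limma-voom on the recovered reads, and Fisher's exact test of called genes per list. Chromosomes and gene order came from NCBI RefSeq and GENCODE annotations of GRCm38, by symbol, for 98.7% of the tested genes. Tests of gene order used 10000 random draws. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.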

Results

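Liver RNA was profiled by RNA sequencing in knockout mice and in wild-type (WT) mice, all given lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria) at 15 mg/kg into the peritoneal cavity and sampled 6 h later. There were 3 libraries per genotype and no untreated livers, so the single comparison asks how the liver under endotoxin differs in the knockout, and the response to LPS itself cannot be read. The deposited values were FPKM for 19613 rows of genes, of which 9218 passed the filter on low values. Whole read counts recovered from the FPKM steps came to 32656002, 31826603 and 41638311 reads in knockout (KO) replicates 1 to 3 and to 27069318, 31342116 and 24087946 reads in WT replicates 1 to 3. Nothing in the labels says that the 3 libraries of a genotype came from separate animals, so p-values measure only the spread between these libraries.

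The genes that passed after scaling included members of the major urinary protein (Mup) and Cyp2c families, heat shock proteins and chaperones of the endoplasmic reticulum, while no gene of the lists of inflammatory cytokines and positive acute-phase proteins passed and 1 chemokine, Cxcl5, did. As deposited, 2703 of the 9218 genes passed an adjusted p of 0.05 (limma), 2648 higher and 55 lower in KO. The median log2 fold change over all tested genes was 0.45, and after median-of-ratios scaling it was -0.00498. With that shift removed, 99 genes passed, 44 higher and 55 lower in KO. Of the 99, 73 had also passed in the deposited values with the same direction, 44 higher and 29 lower. The other 26, all lower, passed only after scaling. The shift raised values in KO, so the overlap of the higher genes is little evidence of its own. Fold changes below are therefore given relative to the shift, from the scaled values, unless the deposited values are named. In the scaled values 1862 genes (20.2%) had no overlap between KO and WT, where chance gives 10%. The count of 99 fell to 20 without KO replicate 1, to 45 without KO replicate 3, to 48 without WT replicate 2 and to 54 without WT replicate 3, and 19 of the 99 passed with any 1 library left out, among them Mup5, Mup9, Mup10, Cyp2c37, Cyp2c39, Cyp2c50, Hsph1, Pctp and Tmc5. The 19 also held the pseudogene Rps13-ps1 (log2 fold change -3.81, limma adjusted p = 1.21e-06) and the predicted genes Gm8730 (-4.21, 0.000144) and Gm6278 (-2.48, 0.000354). The naming rule leaves such genes out, and these were named after their values were seen. How reads that match several genes were assigned is not given in the sources used here, so the values of these genes are uncertain. The count of 2703 went to 5265, 546 and 382 without KO replicates 1, 2 and 3 and to 651, 416 and 4598 without WT replicates 1, 2 and 3.

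**Figure D1:**
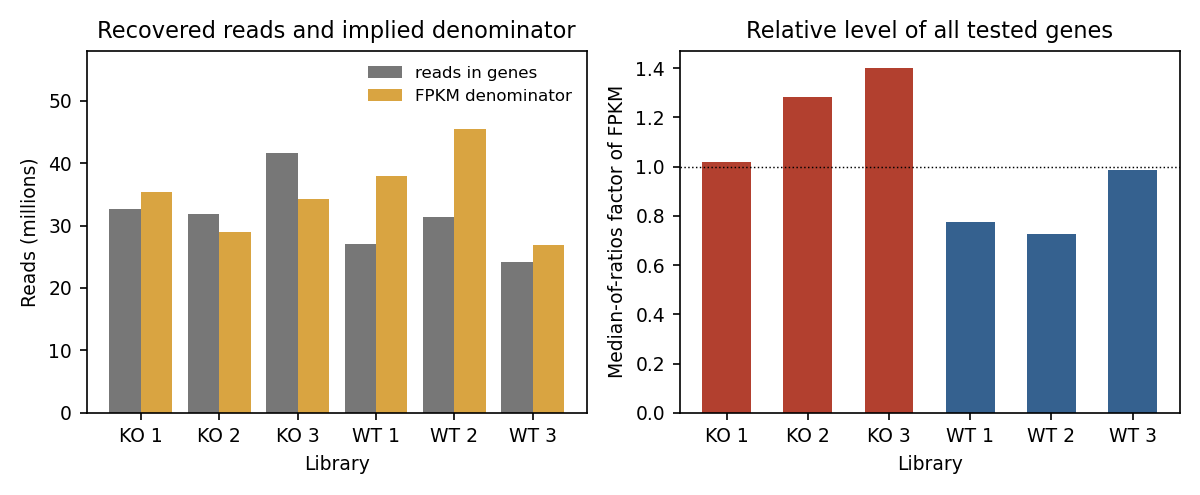
Left, reads in genes recovered from each library's FPKM values (grey) beside the denominator that the same values imply (yellow), on an axis of reads. Right, the median-of-ratios factor of each library over the tested genes, from 0.724 in WT replicate 2 to 1.40 in KO replicate 3; all 3 KO factors lie above all 3 WT factors.

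**Figure D2:**
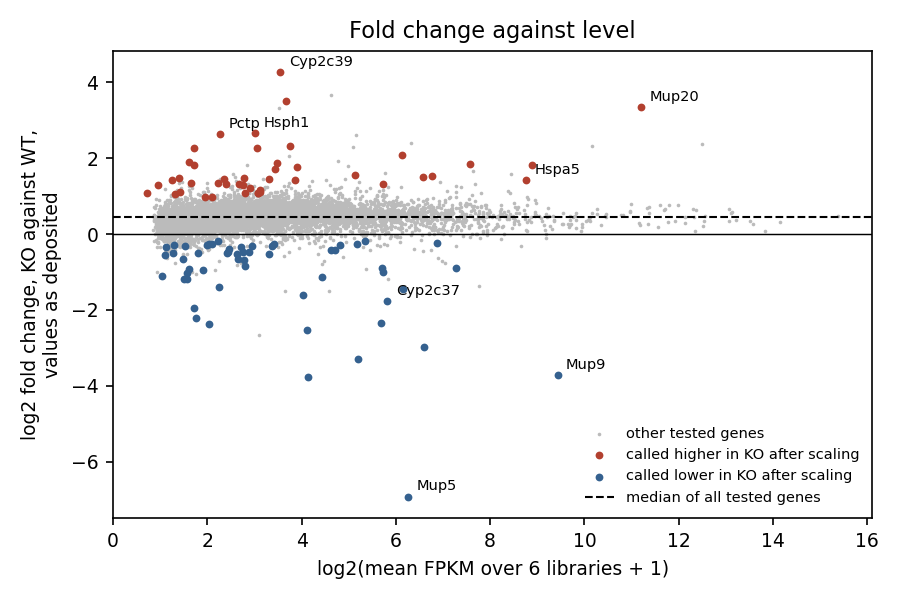
The log2 fold change of each tested gene in the values as deposited (vertical axis) against the log2 of its mean FPKM plus 1 (horizontal axis). Red and blue points are the 44 genes higher and the 55 genes lower in KO after scaling; the dashed line is the median of all tested genes, 0.45.

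Among the Mup genes, which code for the lipocalins that male mice excrete in urine, members moved in opposite directions. Mup5 averaged 180 ± 61.6 FPKM in WT and 0.151 ± 0.129 FPKM in KO (SD, n = 3), a log2 fold change of -7.23 (limma adjusted p = 4.25e-06). Mup9 (-4.30, adjusted p = 0.00245), Mup10 (-3.52, adjusted p = 0.00289) and Mup2 (-2.89, adjusted p = 0.0126) also fell. Mup20, the male pheromone darcin, rose from 590 ± 356 to 3525 ± 1093 FPKM (SD, n = 3; log2 fold change 2.77, adjusted p = 0.0382). Mup11, Mup7 and Mup14 passed in the deposited values with log2 fold changes of 2.41, 2.37 and 2.33, but their adjusted p after scaling was 0.0884, 0.222 and 0.0888. Mup20 did not pass without KO replicate 1, 2 or 3 or without WT replicate 1 (adjusted p = 0.169, 0.0798, 0.0997 and 0.0582), nor Mup2 without KO replicate 1 or WT replicate 3 (0.0712 and 0.0622). Mup14 passed after scaling without KO replicate 2 (adjusted p = 0.00618). In all, 5 of the 20 tested Mup genes passed after scaling, 1 higher and 4 lower, pseudogenes not counted. The pseudogene Mup-ps16 also rose (log2 fold change 2.04, adjusted p = 0.000489; named after its value was seen).

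The Cyp2c genes, cytochromes P450 that oxidise drugs, steroids and fatty acids, showed the same split. Cyp2c39 rose from 0.173 ± 0.012 FPKM in WT to 17.3 ± 1.47 FPKM in KO (SD, n = 3; log2 fold change 3.96, adjusted p = 1.21e-06). Cyp2c37 fell from 106 ± 28.1 to 20.04 ± 0.762 FPKM (log2 fold change -2.32, adjusted p = 0.000873) and Cyp2c40 from 37.9 ± 25.6 to 2.89 ± 0.334 FPKM (-3.03, adjusted p = 0.0346). Cyp2c40 passed without WT replicate 3 but with none of the other libraries left out (adjusted p from 0.071 to 0.151). Cyp2c69 had a log2 fold change of -3.06 that did not pass after scaling (adjusted p = 0.0773, but 0.000585 without WT replicate 3). Of the 13 tested Cyp2c genes, 6 passed after scaling, 1 higher and 5 lower. Mup and Cyp2c genes are families of close paralogs, and how the authors assigned reads that match several members is not given in the sources used here, so the values of single members are uncertain.

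**Figure D3:**
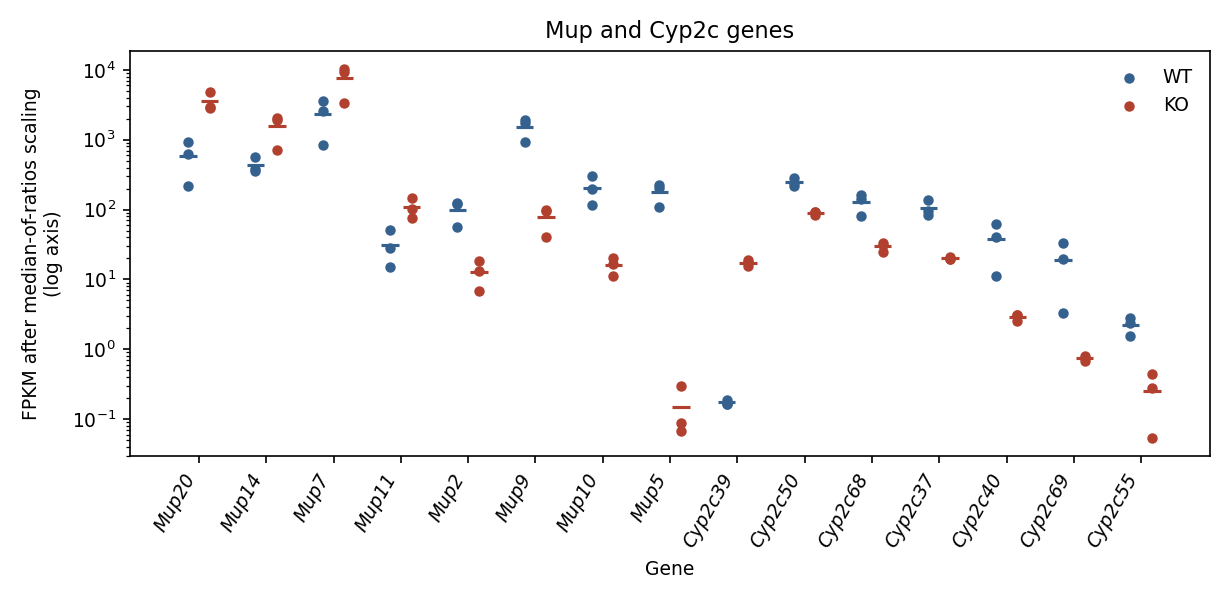
Scaled FPKM of Mup and Cyp2c genes on a log axis, with 1 point per library and a bar at the group mean (blue WT, red KO, 3 libraries each). Mup5 lies above 100 FPKM in every WT library and below 1 FPKM in every KO library, and Cyp2c39 lies below 1 FPKM in every WT library and above 10 FPKM in every KO library.

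Some genes of the unfolded protein response and some heat shock genes rose in KO. Of the 32 tested genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, 7 rose after scaling, none fell, and 27 had a positive fold change (17 rose when adjusted over the list alone). Sdf2l1 rose from 31.9 ± 6.57 to 93.0 ± 18.2 FPKM (log2 fold change 1.52, adjusted p = 0.0111), Creld2 from 99.1 ± 4.78 to 243 ± 36.6 FPKM (1.27, adjusted p = 0.00923) and Derl3 from 0.487 ± 0.213 to 3.48 ± 1.61 FPKM (1.53, adjusted p = 0.0364; SD, n = 3 throughout). Hspa5, which codes for the main chaperone of that compartment, rose from 287 ± 23.2 to 518 ± 59.5 FPKM (0.84, adjusted p = 0.0364); Hspa5, Dnajb9, Pdia4 and Hyou1 were named after their values were seen. Of the 20 tested heat shock genes, 6 rose after scaling, none fell, and 18 had a positive fold change (12 rose when adjusted over the list alone). Hsph1 rose from 1.47 ± 0.568 to 10.7 ± 2.49 FPKM (2.25, adjusted p = 0.00271), Hspa1b from 2.15 ± 0.645 to 10.8 ± 5.25 FPKM (1.83, adjusted p = 0.0380) and Dnajb1 from 4.53 ± 0.492 to 13.8 ± 4.49 FPKM (1.38, adjusted p = 0.0222). The median log2 fold change was 0.51 for the unfolded protein response and 0.55 for the heat shock proteins. Both lists were called higher by camera with a preset correlation, in the deposited values (adjusted p = 3.03e-19 and 1.18e-16) and after scaling (6.53e-13 and 4.21e-10). With an estimated correlation neither call held as deposited (adjusted p = 0.740 for each) or after scaling (0.610 and 0.756). Without KO replicate 1 the members that passed went from 7 to 0 and from 6 to 1; with each other library left out they were 1 to 6 of the unfolded protein response (1 without WT replicate 3, 2 without WT replicate 2, 3 without KO replicate 2 or KO replicate 3) and 2 to 4 of the heat shock genes (2 without WT replicate 2, 3 without KO replicate 2, WT replicate 1 or WT replicate 3).

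**Figure D4:**
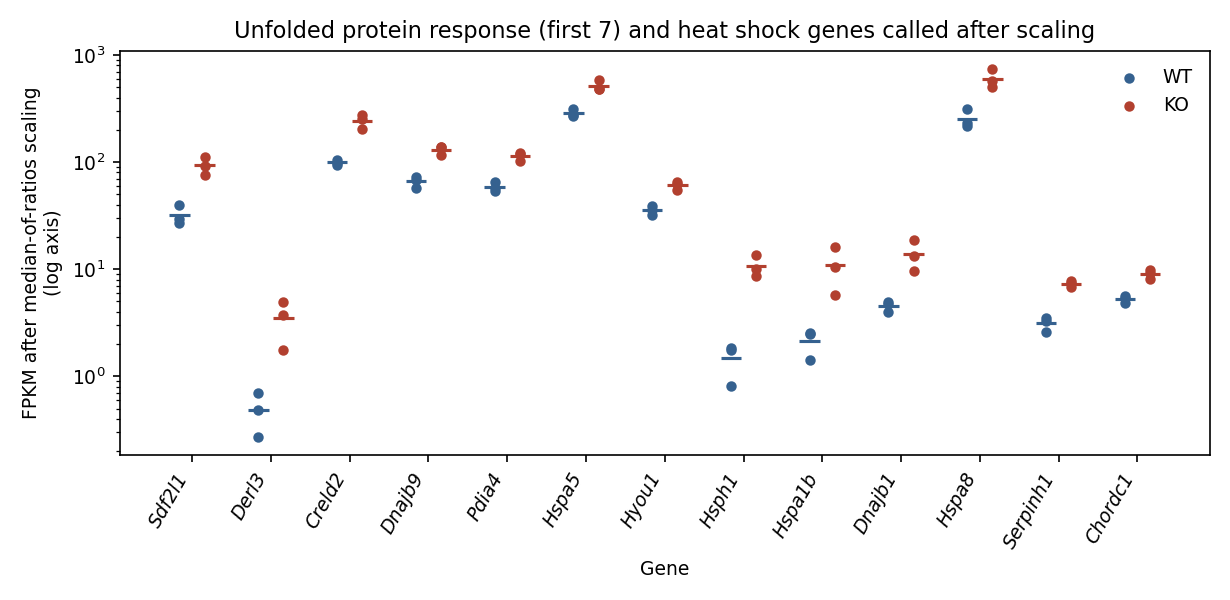
Scaled FPKM, on a log axis, of the 7 unfolded protein response genes (Sdf2l1 to Hyou1) and the 6 heat shock genes (Hsph1 to Chordc1) that passed after scaling, with 1 point per library and a bar at the group mean. For each of these genes the 3 KO libraries lie above the 3 WT libraries.

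Genes outside these families also changed. Pctp, which codes for a phosphatidylcholine transfer protein, rose from 0.428 ± 0.139 to 6.08 ± 1.42 FPKM (SD, n = 3; log2 fold change 2.30, adjusted p = 0.000438), and Vnn1, a pantetheinase gene, from 4.14 ± 0.807 to 18.0 ± 6.96 FPKM (1.82, adjusted p = 0.0222). Tmc5 fell from 5.14 ± 0.641 to 0.277 ± 0.162 FPKM (-2.27, adjusted p = 0.000172) and Trim34b from 7.29 ± 4.14 to 0.184 ± 0.0429 FPKM (-2.66, adjusted p = 0.0143). Angptl8, an insulin-induced inhibitor of triglyceride clearance, fell from 28.4 ± 8.84 to 5.88 ± 2.79 FPKM (-2.13, adjusted p = 0.0177). Without KO replicate 1 the adjusted p of Vnn1, Trim34b and Angptl8 was 0.0981, 0.0944 and 0.112, and that of Vnn1 also exceeded 0.05 without KO replicate 3, WT replicate 2 or WT replicate 3, that of Trim34b without KO replicate 3 or WT replicate 3, and that of Angptl8 without WT replicate 2 or WT replicate 3. Trim12a and Trim30d were among the 10 largest rises in the deposited values (3.34 and 2.63) but did not pass after scaling (adjusted p = 0.115 and 0.126). For both, WT replicate 1 stood apart from the other WT libraries, with 5.81 against 0.0305 and 0.0386 FPKM for Trim12a and 22.3 against 5.85 and 4.41 FPKM for Trim30d as deposited, and without it both passed after scaling (log2 fold change 4.03 and 2.79, adjusted p = 5.8e-05 and 0.00278). Trim34b stood, as deposited, at 2.19 FPKM in WT replicate 1 against 7.99 and 7.91 FPKM in the other WT libraries. Trim34b, Trim12a and Trim30d are members of a family of paralogs, with the same uncertainty as above.

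None of the single inflammatory and liver genes fixed beforehand passed after scaling. Tnf averaged 6.98 ± 1.22 FPKM in KO and 7.74 ± 2.61 FPKM in WT, Il6 2.68 ± 0.226 and 2.71 ± 1.14 FPKM, Il1b 27.2 ± 3.53 and 22.6 ± 2.32 FPKM, and Cxcl10 198 ± 43.5 and 304 ± 94.6 FPKM (SD, n = 3). Saa1, an acute-phase gene, stood at 2646 ± 227 FPKM in KO and 2417 ± 91.7 FPKM in WT. After scaling, the log2 fold changes of Tnf, Il6, Il1b, Cxcl1, Ccl2, Cxcl10, Saa1, Lcn2, Socs3, Nfkbia and Alb ranged from -0.60 (Cxcl10) to 0.25 (Il1b), and their adjusted p from 0.333 (Cxcl10) to 0.967 (Socs3). In the deposited values Il1b (0.81, adjusted p = 0.00821) and Saa1 (0.70, adjusted p = 0.0375) passed. An exact permutation test of such a difference cannot go below p = 0.1 with 3 libraries against 3. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, lay between 0.033 and 0.0812 FPKM in every library and was not tested. None of the 15 tested inflammatory cytokines and none of the 33 positive acute-phase genes passed after scaling with limma (3 and 2 had an unadjusted p under 0.05) or with limma-voom, and 1 of 17 chemokines did, Cxcl5, which rose (log2 fold change 0.72, adjusted p = 0.0300; named after its value was seen). Cxcl5 passed without WT replicate 1 but with none of the other libraries left out (adjusted p from 0.0865 to 0.134). Adjusted over the list alone, 2 of the cytokines fell and 1 of the chemokines rose.

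Of the lists of immune genes, 4 were called lower in KO after scaling by camera with a preset correlation and 5 others were not. Over lists of every kind, 7 of the 10 splits of the libraries, the real one included, called as many lists after scaling. The number of lists called therefore does not set the real split apart. With an estimated correlation none of the 4 calls held (adjusted p = 0.756 for each). The 34 NF-kB response genes had a median log2 fold change of -0.21 after scaling, with 30 of 34 below 0, and 1 member passed (3 when adjusted over the list alone). That member was Nos2, the inducible nitric oxide synthase, which fell from 9.15 ± 1.06 to 4.19 ± 0.275 FPKM (SD, n = 3; log2 fold change -0.97, adjusted p = 0.00960, and 0.0694 without KO replicate 1; named after its value was seen). The 3 NF-kB members with the lowest p in the deposited values, Selp, Ptgs2 and Olr1, had positive values after scaling of 0.44, 0.40 and 0.31, and none passed. The 12 MHC class I genes had a median of -0.29, and 1 passed, H2-Q6, which fell from 9.01 ± 0.717 to 3.46 ± 0.757 FPKM (-1.18, adjusted p = 0.0111, and 0.0556 without KO replicate 1). H2-M3 and H2-T22 had values of 0.04 and -0.14. H2 genes are paralogs, and the value of H2-Q6 is uncertain in the same way. The 42 interferon-stimulated genes and the 32 interferon-gamma response genes had medians of -0.19 each and no member that passed with limma (11 and 7 had an unadjusted p under 0.05) or limma-voom. Camera with a preset correlation called the NF-kB list lower in the deposited values (adjusted p = 0.0284) and after scaling (0.000272), and the MHC class I list likewise (0.0189 and 0.000415), and the interferon lists after scaling only (0.000415 and 0.00191; with quantile normalization 0.015 and 0.0742). As deposited, the NF-kB call was lost without KO replicate 1, WT replicate 2 or WT replicate 3 (adjusted p = 0.0763, 0.119 and 0.185) and the MHC class I call without WT replicate 2 (0.177). Neither deposited call held in camera with an estimated correlation (adjusted p = 0.975 for each). After scaling, the call of the interferon-stimulated genes was lost without KO replicate 3 or WT replicate 2 (0.0850 and 0.0501) and that of the interferon-gamma genes without KO replicate 3 (0.0594). Components of the TLR4 pathway (0.0605), the IL-6 and STAT3 axis (0.0605), inflammasome and cell death genes (0.256), cytokines (0.486) and chemokines (0.674) were not called after scaling; the TLR4 list passed without KO replicate 2, WT replicate 1 or WT replicate 2 (0.0449, 0.0487 and 0.0292) and the IL-6 list without KO replicate 1 or WT replicate 1 (0.0376 and 0.0149).

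In hepatocyte metabolism, markers of the pericentral zone, around the central vein, lay lower in KO. All 17 tested pericentral markers had a negative log2 fold change after scaling, with a median of -0.40, and 2 passed (9 when adjusted over the list alone), both Cyp2c genes. Cyp2c50 fell from 245 ± 31.3 to 88.4 ± 5.24 FPKM (SD, n = 3; log2 fold change -1.45, adjusted p = 0.00289), beside Cyp2c37 above. The most abundant pericentral markers did not pass after scaling: Cyp2e1 had a log2 fold change of -0.24, Rgn of -0.58 and Cyp1a2 of -0.42, and Glul, which lines the central vein, of -0.04. Camera called the list lower (adjusted p = 8.01e-09 as deposited and 2.37e-09 after scaling, but 0.740 and 0.422 with an estimated correlation). Of the 61 cytochrome P450 and drug metabolism genes, 1 rose and 5 fell after scaling, all of them Cyp2c genes (4 and 13 when adjusted over the list alone). Camera called this list lower (0.00763 as deposited and 0.00191 after scaling, but 0.975 and 0.756 with an estimated correlation). This call was lost without KO replicate 2 (adjusted p = 0.342 as deposited and 0.182 after scaling) and without WT replicate 1 (0.551 and 0.270). The 29 fatty acid and triglyceride synthesis genes had a median of -0.31 and were called lower by camera (0.00041 and 0.000169, but 0.975 and 0.756 with an estimated correlation). Their 1 member that passed was Gpam, the acyltransferase that starts glycerolipid synthesis, which fell from 6.49 ± 1.12 to 2.80 ± 0.285 FPKM (-0.97, adjusted p = 0.0157, but 0.105 without KO replicate 1 and 0.0664 without KO replicate 3; named after its value was seen). Dgat1, Dgat2 and Me1, of lowest p in the deposited values, had values of 0.30, 0.07 and 0.02. The 30 cholesterol synthesis and uptake genes had a median of 0.23 and no member that passed after scaling with limma (10 had an unadjusted p under 0.05) or limma-voom. Camera called these genes higher as a list (0.00041 and 0.00413, but 0.975 and 0.756 with an estimated correlation, and 0.170 after scaling without WT replicate 3). Among them Mvd had 0.82, Sqle 0.73 and Cyp51 0.63.

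The markers of red blood cells and of male-biased liver expression were called higher by camera in the deposited values only (adjusted p = 0.0275 and 8.09e-06; 0.127 and 0.151 after scaling; with an estimated correlation, adjusted p = 0.740 and 0.975 as deposited). As deposited, the red cell call was lost without KO replicate 1, WT replicate 1 or WT replicate 3 (0.316, 0.0589 and 0.182) and the male-biased call without WT replicate 2 (0.357). After scaling, the red cell list passed without WT replicate 2 (0.00424) and the male-biased list without KO replicate 2 or WT replicate 3 (0.0130 and 0.00764). After scaling none of the 7 red cell markers passed with limma (1 had an unadjusted p under 0.05) or limma-voom; Hba-a1 had a log2 fold change of 0.36, Hbb-b1 of 0.25, Hbb-bt of 0.74 and Alas2 of 0.32. Of the 23 male-biased genes 1 passed, Mup20; Ugt2b38 had 1.76, Mup3 0.08 and Serpina1e 0.20, and none of these passed.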

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

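The alternatives of the scaled results, limma-voom on the recovered reads and the wider use of the scaled values were chosen after seeing the data; the cause of a change was not tested unless one is given. The count of genes called in the deposited values moved with the scaling, with the filter on low values and with weights on the libraries. Against 2703 calls (2648 higher and 55 lower), median-of-ratios scaling gave 99 (44 and 55), upper-quartile scaling 98 (43 and 55), quantile normalization 109 (54 and 55), rescaling to TPM 111 (62 and 49) and limma-voom on recovered reads 122 (70 and 52), so that the share of higher calls went from 98.0% to 44.4%, 43.9%, 49.5%, 55.9% and 57.4%. Of the 99 genes called after scaling, limma-voom with median-of-ratios sizes called 92. Without a filter on low values, where 19201 genes are tested, the counts were 39 (28 and 11) as deposited and 33 (10 and 23) after scaling. A mean of at least 5 FPKM, which tests 4682 genes, gave 1976 (1944 and 32) and 61 (28 and 33). arrayWeights gave 7440 (7367 and 73) and 354 (161 and 193). An adjusted p under 0.1 gave 4673 (4600 and 73) and 220 (104 and 116), and an absolute log2 fold change of at least 1 gave 229 (202 and 27) and 52 (22 and 30). Other pseudocounts and variance models kept each count within 1.5 times.

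With each library left out in turn, the deposited values gave 382 to 5265 calls, 337 to 5211 higher and 41 to 54 lower, and the scaled values 20 to 97, 7 to 43 higher and 13 to 54 lower. The lowest counts came without KO replicate 3 (382) as deposited and without KO replicate 1 (20) after scaling; all 20 were among the 99, and none of the 99 changed sign in any of these 6 fits. Lists called higher ranged over 4 to 8 and lower over 3 to 10 as deposited, and over 3 to 5 and 9 to 17 after scaling, the last with 17 without WT replicate 3.

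Whether the replicate numbers pair the libraries cannot be told from so few. Same-numbered libraries had correlations of their deviations from the group means of 0.33, 0.47 and 0.02 after scaling. KO replicate 2 and WT replicate 2 correlated best with each other, while KO replicate 3 and WT replicate 3 each correlated best with a library of another number. With the replicate block the counts were 5823 (5740 and 83) as deposited and 298 (123 and 175) after scaling, and the lists 8 and 5 as deposited.

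Against 5 lists called higher and 5 lower in the deposited values, the counts were 9 and 2 without a filter, 3 and 11 with median-of-ratios, 3 and 10 with upper-quartile and 3 and 10 with TPM scaling, 2 and 13 with arrayWeights and 3 and 10 with voom. Camera with an estimated correlation called 0 and 0 as deposited and 0 and 0 after scaling (against 3 and 11), and fry 3 and 0 as deposited and 0 and 1 after scaling.

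Among named genes, those that changed sign were uncalled in the deposited values. Median of ratios, upper quartile and quantiles remove the shift by construction. TPM and limma-voom do not fix the median of all genes. In both, however, a library's deposited denominator cancels, so any part of the shift that came from it is removed as well. All these scalings left a median of all genes between -0.00498 (median of ratios) and 0.0852 (TPM), with 0.0788 for limma-voom. For the genes that they turned, the deposited log2 fold changes were Tnf 0.41, Cxcl1 0.33, Ccl2 0.065, Lcn2 0.52, Socs3 0.55, Nfkbia 0.39, Alb 0.27, H2-T22 0.42, Glul 0.54, Cyp2e1 0.34, Cyp1a2 0.15, Rbm3 0.42. With median of ratios the values were Tnf -0.093, Cxcl1 -0.24, Ccl2 -0.50, Lcn2 -0.059, Socs3 -0.021, Nfkbia -0.18, Alb -0.31, H2-T22 -0.14, Glul -0.036, Cyp2e1 -0.24, Cyp1a2 -0.42, Rbm3 -0.12. With upper quartile the values were Tnf -0.092, Cxcl1 -0.24, Ccl2 -0.50, Lcn2 -0.058, Socs3 -0.020, Nfkbia -0.18, Alb -0.30, H2-T22 -0.14, Glul -0.035, Cyp2e1 -0.24, Cyp1a2 -0.42, Rbm3 -0.12. With quantiles the values were Tnf -0.10, Cxcl1 -0.11, Ccl2 -0.43, Lcn2 -0.091, Nfkbia -0.072, H2-T22 -0.033, Cyp2e1 -0.10, Cyp1a2 -0.30, Rbm3 -0.10. With TPM the values were Tnf -0.000404, Cxcl1 -0.14, Ccl2 -0.41, Nfkbia -0.082, Alb -0.20, H2-T22 -0.045, Cyp2e1 -0.14, Cyp1a2 -0.32, Rbm3 -0.023. With voom the values were Tnf -0.034, Cxcl1 -0.16, Ccl2 -0.43, Nfkbia -0.10, Alb -0.22, H2-T22 -0.064, Cyp2e1 -0.16, Cyp1a2 -0.34, Rbm3 -0.043. With arrayWeights Cxcl10 went from -0.024 to 0.28 and Rgn went from -0.0088 to 0.25. With 1 library left out, Ccl2 ranged from -0.21 to 0.28, Cxcl10 ranged from -0.20 to 0.13, Rgn ranged from -0.12 to 0.13.

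For lists, the direction is that of camera, and the value the median log2 fold change less that of all genes. The direction turned for these medians: without a filter interferon-stimulated 0.17, interferon-gamma response 0.17, chemokines 0.17, acute phase 0.31, with arrayWeights male-biased liver genes 0.037, cytokines 0.026, chemokines 0.050, without trend acute phase 0.061, with the replicate block acute phase 0.061. With 1 library left out, cytokines ranged from -0.10 to 0.095, chemokines ranged from -0.11 to 0.11, acute phase ranged from -0.037 to 0.14. None of these lists was called in the deposited values except the male-biased one. The acute-phase median (0.06) was above 0 while camera placed the list below other genes. fry, which does not compare with other genes, tests the deposited shift too, and gave the opposite direction for 9 of the described lists, with deposited medians of 0.27 (NF-kB response genes), 0.26 (MHC class I), 0.37 (cytochrome P450), 0.19 (fatty acid synthesis), 0.35 (interferon-stimulated), 0.37 (interferon-gamma response), 0.42 (cytokines), 0.40 (chemokines), 0.52 (acute phase).

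Of the named genes, 24 were called as deposited but not after median-of-ratios scaling, 12 only after it, and 48 lost their call without a filter. At least 24087946 reads in genes were recovered from each library, and depth limits the genes with few reads.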

Other observations

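The tests of the 3 patterns below were chosen after the result was seen, except those of leaving out single libraries and of Rbm3 for the stress genes; the Fisher tests of called genes per list, the lists with single libraries left out after scaling, the counts of members at an unadjusted p and the genes named here were chosen then too.

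Lists of metabolic, plasma protein and mitochondrial genes, not called as deposited, were called lower in KO after scaling. The 48 genes of the urea cycle and amino acid catabolism had a median log2 fold change of -0.19, with 41 below 0 (camera adjusted p = 0.000272), and the 33 plasma proteins of hepatocytes -0.20, with 29 below 0 (0.00413). The 13 mitochondrially encoded genes were all below 0, with a median of -0.32 (0.0443), and the 72 nuclear-encoded genes of oxidative phosphorylation had -0.09, with 62 below 0 (0.0191). Each call was lost with an estimated correlation (adjusted p = 0.756 for each), and with quantile normalization those of the plasma proteins (0.119), the mitochondrially encoded genes (0.178) and the nuclear-encoded genes (0.720) were lost as well. The call of the nuclear-encoded genes was also lost with TPM scaling (0.0840) and limma-voom on recovered reads (0.0536), and that of the mitochondrially encoded genes with upper-quartile scaling (0.0503). No member of the urea cycle, mitochondrially encoded and nuclear-encoded lists passed with limma (11, 1 and 0 had an unadjusted p under 0.05) or limma-voom, and of the plasma proteins only Mup20 did, which rose with both. Leaving out 1 library ended the call of the urea cycle list (without WT replicate 1, 0.0668), of the plasma proteins (without KO replicate 2, 0.278, or WT replicate 1, 0.0668), of the mitochondrially encoded genes (without KO replicate 1, 0.240, KO replicate 3, 0.0936, WT replicate 2, 0.529, or WT replicate 3, 0.163) and of the nuclear-encoded genes (without KO replicate 2, 0.205, KO replicate 3, 0.303, WT replicate 1, 0.0896, or WT replicate 2, 0.310). Of the other lists of liver functions, bile acid synthesis and transport (0.0618), coagulation (0.106), complement (0.151), positive acute-phase proteins (0.299) and periportal markers (0.981) were not called after scaling; bile acid genes passed without KO replicate 1 (0.00940), WT replicate 2 (0.00939) or WT replicate 3 (0.0463) and coagulation without KO replicate 1 (0.0202) or KO replicate 3 (0.0271). Mitochondrial transcripts took 18.2%, 30.2% and 20.1% of the FPKM in KO replicates 1 to 3 and 17.8%, 31.0% and 26.9% in WT replicates 1 to 3, so the groups overlapped.

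Other lists held single genes that passed. Cited2 fell from 6.40 ± 0.406 to 3.05 ± 0.190 FPKM (SD, n = 3; log2 fold change -0.87, limma adjusted p = 0.00923) and Slc37a4, the glucose-6-phosphate transporter, from 35.8 ± 0.908 to 19.7 ± 2.29 FPKM (-0.84, 0.0192), both among the 31 genes of gluconeogenesis, glycogen and FOXO targets. Ccnd1, which codes for cyclin D1, fell from 3.78 ± 1.42 to 0.881 ± 0.0952 FPKM (-1.30, adjusted p = 0.0276) and the clock gene Npas2 from 1.85 ± 0.153 to 0.599 ± 0.284 FPKM (-0.85, 0.0336). Without KO replicate 1 none of these passed (adjusted p = 0.0694, 0.113, 0.138 and 0.157), and each but Cited2 also lost its call without other libraries. The markers of neutrophils (15), monocytes (8), Kupffer cells (14), sinusoidal endothelial cells (11), stellate cells (7), cholangiocytes (9) and adipocytes (5) had no member that passed with limma (2, 0, 3, 2, 0, 1 and 1 had an unadjusted p under 0.05) or limma-voom, and camera called none of these lists in the 6 libraries (adjusted p from 0.0605 to 0.899). With 1 library left out, Kupffer cell markers were called lower without KO replicate 1 (0.0448), KO replicate 3 (0.00696) or WT replicate 3 (0.000648), sinusoidal endothelial markers without KO replicate 3 (0.0298) or WT replicate 3 (0.00105), and those of neutrophils and stellate cells without WT replicate 3 (0.0418 and 0.0441). 8 lists, MHC class II and the markers of lymphocytes among them, had under 5 tested members.

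Most genes lay higher in KO as deposited, with a median log2 fold change of 0.45. The 20 genes with most recovered reads do not account for it, since the share of reads outside them was 1.01 times as high in KO as in WT. COX1, whose reads were not recovered, was left out of this share, so its part was not tested. Denominators that do not follow the reads of their own library are a candidate explanation, since the recovered reads made up as much as 121.4% of the denominator in KO replicate 3 and 69.0% in WT replicate 2. Whether the denominators belong to other libraries cannot be told, since matching by rank (86.0% to 93.2% of the denominator) always narrows the range. With each library's own recovered reads, without COX1, as its total (limma-voom), the deposited denominators drop out, and the median was 0.08. Values divided by a library's own reads, as FPKM is meant to be, carry no difference in RNA per cell.

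Genes that passed after scaling lay near each other on chromosomes, with 43 of 99 having another within 10 tested genes, against a mean of 19.07 in 10000 random draws (permutation p = 0.0001, the smallest they can give). Reads shared within the Mup, Cyp2c and Trim families do not cover this, since without them it was 30 of 85 (mean of draws 14.32, permutation p = 0.0021). The most genes that passed lay on chromosomes 19 (15 of 350 tested), 7 (13 of 683) and 4 (12 of 612). What accounts for the neighbours, inside these families as well as outside them, stays open. A difference in strain between the groups is among the possibilities for both, and was not tested. An effect of the knockout on genes beside the targeted one could reach only the chromosome of that gene. Neighbouring genes that passed lay on chromosomes 19, 7 and 4 among others, so such an effect cannot cover them all.

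The lists of the unfolded protein response and heat shock proteins were called higher in KO after scaling by camera with a preset correlation, but not with an estimated one (adjusted p = 0.610 and 0.756). Fisher's exact test, which treats genes as independent, found more genes that passed in both lists than expected (7 of 32 against 0.344 expected and 6 of 20 against 0.215, adjusted p = 1.02e-06 for each) and, of the other lists, only in cytochrome P450 (6 of 61, 0.000681). The lowest median of the 2 lists over 4 other scalings was 0.51. These scalings leave similar medians of all genes (-0.00366 to 0.0852), so they cannot exclude the scaling, and show only that both lists lay above other genes. A single library does not account for the higher medians of the 2 lists, since the lowest with 1 left out was 0.39 (unfolded protein response, without WT replicate 2). Without KO replicate 1, however, the members that passed went from 7 to 0 and from 6 to 1. A higher body temperature of the knockout mice cannot be told apart from an effect of the knockout: of 2 cold-induced genes, Cirbp fell from 4.50 ± 0.591 to 2.36 ± 0.376 FPKM (SD, n = 3; adjusted p = 0.0484, and over 0.05 with any library left out), while Rbm3 had a log2 fold change of -0.12 with overlapping groups (adjusted p = 0.725).

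The 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 2703 genes as deposited and 99 after scaling, and the highest of the others 34 and 0, so that 1 split of 10 reached each real count. It called 10 lists as deposited and 14 after scaling, and the highest of the others 24 and 18; 9 and 7 of the 10 splits called as many lists, the real one included.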
